A study of Homo sapiens with 12 samples.

How the data were processed

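Total RNA of MDA-MB-231 cells was hybridised to 12 Affymetrix whole-transcript arrays, 1 array per sample. The labels place the samples in 4 groups of 3: untreated cells, cells given TNFα at 40 ng/ml, cells given apigenin at 40 µM, and cells given both, all for 24 h. Per the labels' protocols, RNA was isolated with TRIzol and chloroform, brought to a common concentration and biotin-labelled with a whole-transcript kit. The deposited values are log2 expression values per probe set made with Affymetrix Expression Console, per the submitters' processing notes. Its version, its summary algorithm and its settings are not given in the sources used here, so whether the authors' step was one kind of background correction and normalisation or another stays unknown. The log scale itself was checked on the values: they ran from 0.536 to 12.495 with none missing, and the medians of the 12 arrays lay between 2.091 and 2.159. The quartiles of the arrays were close to each other, as between-array normalisation would leave them, and no centring by gene was present. No genome build is named in the sources used here, and no coordinates are given.

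The table held 53617 probe sets. The platform's probe table gave exactly 1 gene symbol to 23871 of them and several symbols to 1842, while 27904 were unnamed here and entered no comparison. Symbols were updated through the gene identifier for 22569 probe sets, which changed 90 names, and 1302 kept the symbol of the array's own annotation. A probe set was kept when it reached the 25th percentile of its own array on at least 3 arrays, a level between 1.597 and 1.645 on the log2 scale. This left 21895 probe sets for 20572 genes. Of these genes, 549 had several kept probe sets and were read from the one with the highest mean over the 12 arrays. Other probe sets of a gene could move the opposite way: this was so for 3 of the 6 called genes with several probe sets between TNFα and control, and for 21 of 66 between apigenin and control.

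A linear model with 4 group means was fitted to the 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings), so that all groups shared 1 residual variance per gene with 8 residual degrees of freedom. There were 6 comparisons: TNFα against control, apigenin against control, the combined treatment against TNFα, against apigenin and against control, and the interaction, which is the TNFα response with apigenin minus the TNFα response without it. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over the 20572 genes of a comparison. Every adjusted p of a single gene comes from this limma fit. Fold changes are differences of mean log2 values with the standard error (SE) of the moderated fit; a value near the lower end of the scale understates the change in RNA. The labels number the samples 1 to 3 within each group and do not state whether the 3 came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The controls were untreated; per the labels the treatments were prepared in HBSS, and whether the controls received the same solution or a solvent is not given in the sources used here. For 3 arrays against 3 the smallest two-sided exact p is 0.1, and groups that do not differ fail to overlap with a chance of 10%.

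Of 33 gene lists written before the data were examined, 32 had at least 3 measured members and were tested with camera (limma) at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Beside each list stand the number of members called over all genes and the number called when adjusted over the list alone. Camera with a correlation estimated from the data and fry were run as alternatives. The genes named in the text follow a rule set before the data were examined. It takes the called genes with the largest changes whose groups do not overlap (8 in each direction for the first 3 comparisons, 6 for the interaction without the overlap condition, 4 for the others, without non-coding and provisional symbols). It adds up to 4 called members of each list in each comparison, and a panel of 31 genes, 4 of which are not analysed here. The few genes named outside this rule are said to be so where they appear. Correlations between comparisons were computed across genes, which are not independent replicates.

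The fit was tested on simulated data before use, with 20572 genes drawn from the measured means and residual spreads and 100 genes changed at each size. For TNFα against control, 91.0% of genes changed by 1 on the log2 scale and 100% of those changed by 2 were recovered, with 8 false calls among 199. For the interaction, 61.0% and 100% were recovered, so a difference of response of about 1 on the log2 scale was often missed with 3 arrays per group. The simulation called 169 genes for the interaction, against 11 in the data. Fewer calls make the adjusted threshold stricter, so recovery in the data is likely lower than these interaction rates. In the simulation of lists none of 30 unmoved lists was called. Simulated genes were drawn independently of each other, so this does not test the lists under correlation between genes. In the data that correlation was estimated at 0.207 for the G2/M and mitosis list and 0.378 for the small nucleolar RNA list. The number of arrays limits the precision: the median residual SD was 0.187.

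Alternatives fixed before the data were examined were quantile normalisation, median centring, no filter, a filter at the 50th percentile, all probe sets, a trended and robust variance, no variance moderation and array weights. Further ones were minimum changes of 1.5-fold and 2-fold, the replicate number as a block, only the arrays of the groups compared, and each array left out in turn. Added after seeing the data were a filter at a log2 value of 4, a fit without the 4 arrays numbered 3, and a fit with the median of the small nucleolar RNA list of each array as a covariate, for ribosomal proteins and zinc finger genes also with an estimated correlation. A comparison of response ratios restricted to genes with controls above the median of all genes was added in the same way.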

Results

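The study measured gene expression in MDA-MB-231 cells, an established line from a pleural effusion of triple-negative breast cancer, after 24 h with TNFα at 40 ng/ml, apigenin at 40 µM, both or neither. TNFα is an inflammatory cytokine that activates the transcription factor NF-κB, and apigenin is a plant flavone. Each of the 4 groups had 3 arrays. Values are deposited log2 expression values with array medians of 2.099 to 2.159 in control, 2.091 to 2.143 with TNFα, 2.122 to 2.138 with apigenin and 2.116 to 2.153 with both, and 19.5% to 21.6% of the probe sets of an array lay above a log2 value of 4. Arrays of the same group correlated at r = 0.983 to 0.991 across genes and arrays of different groups at 0.966 to 0.990, and no pair of arrays held identical values. The first principal component, with 38.3% of the variance, separated the 6 arrays with apigenin (scores 17.2 to 29.2) from the 6 without it (-32.2 to -17.5). The second held 18.8%, and on it the array numbered 3 had the lowest score of its group in all 4 groups.

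The first comparison asked what TNFα alone changed. Interleukin-8 (CXCL8, probe set 16967771) rose from 3.26 ± 0.35 (mean log2 value ± SD, n = 3) to 7.63 ± 0.10, a difference of 4.36 (SE 0.19, 20.6-fold, adjusted p = 4.7e-08). IL1A, which encodes the cytokine interleukin-1α, rose from 1.87 ± 0.10 to 6.20 ± 0.11, a difference of 4.33 (SE 0.15, adjusted p = 3.9e-09). The ubiquitin-editing NF-κB inhibitor TNFAIP3 rose by 3.12 (SE 0.15), the costimulatory receptor TNFRSF9 by 2.93, the adhesion molecule ICAM1 by 2.63, the matrix protease ADAMTS9 by 2.39, and complement C3 and the lysosomal protease CTSS by 2.31 each. Among the genes that fell were VIPR1, a neuropeptide receptor (log2 fold change -1.50, SE 0.13, adjusted p = 2.7e-05), the laminin-binding integrin ITGB4 (-1.04) and the lipid phosphatase PLPP4 (-1.02).

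In the list of NF-κB signalling and feedback genes 21 of 36 measured members rose, none fell and 15 were not called over all genes; adjusted over the list alone, 26 rose. The median log2 fold change of the list was 0.76 (camera adjusted p = 5.2e-38; adjusted p = 0.0215 with an estimated correlation). Besides TNFAIP3 and TNFRSF9, its members included the kinase IKBKE (2.17, SE 0.27), the adaptor TRAF1 (1.96, SE 0.20) and the inhibitor NFKBIA (1.69, SE 0.15). Of the chemokines and cytokines 14 of 32 rose and none fell, and 18 rose and 1 fell when adjusted over the list alone (median 0.71, camera adjusted p = 1.7e-22; adjusted p = 0.00266 with an estimated correlation). Members other than CXCL8 and IL1A included CXCL10 (1.65, SE 0.21), a chemoattractant of T cells, IL6 (1.74, SE 0.29) and the monocyte chemoattractant CCL2. CCL2 stood at 1.77 ± 0.05 in control and 2.90 ± 0.28 with TNFα (log2 fold change 1.13, SE 0.14, adjusted p = 0.00114), both in the low part of the scale.

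Smaller shifts were called in 13 other lists, and none of these calls held with an estimated correlation. The luminal breast epithelial markers were among them (none of 16 called in the limma fit over all genes, 2 lower adjusted over the list alone, median -0.13, adjusted p = 0.00689; adjusted p = 0.175 with an estimated correlation). The antigen presentation and adhesion list rose (3 of 28 members called, 6 adjusted over the list alone, adjusted p = 1.8e-06; adjusted p = 0.216 with an estimated correlation), led by ICAM1 and the dendritic-cell marker CD83 (2.02). The ribosome biogenesis list rose (3 of 40 called, 15 over the list alone, median 0.32, adjusted p = 2.8e-11; adjusted p = 0.216 with an estimated correlation). The G2/M and mitosis list fell (4 of 65 called, 14 over the list alone, median -0.23, adjusted p = 7.1e-12; adjusted p = 0.216 with an estimated correlation). Of the matrix protease and invasion list 3 of 40 members rose and 1 fell, 10 and 3 over the list alone (adjusted p = 0.0263; adjusted p = 0.697 with an estimated correlation). With quantile normalisation this list lost its call (camera adjusted p = 0.0613). The gelatinase MMP9 rose by 1.38, the interstitial collagenase MMP1 by 1.01 and the urokinase receptor PLAUR by 0.90, while ITGB4 fell. The small nucleolar RNA list also fell (none of 173 members called in the limma fit over all genes or adjusted over the list alone, median -0.26, adjusted p = 2.0e-08; adjusted p = 0.687 with an estimated correlation). The medians of that list on the TNFα arrays were 5.13, 5.96 and 4.75. Interferon-stimulated genes had a median of 0.02 (1 of 48 called lower, SAMD9; adjusted p = 0.456).

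TNFα against control gave 205 called genes, 160 higher and 45 lower, of which 71 changed at least 2-fold; 2387 genes had an unadjusted p below 0.05. Quantile normalisation called 181 higher and 123 lower, so the share of higher calls moved from 78.0% to 59.5%. The count was 98 without control replicate 1, 131 without control replicate 2, 103 without TNFα replicate 1, 314 without TNFα replicate 2 and 107 without TNFα replicate 3. Without control replicate 3, 222 genes were higher and 30 lower. Of the 50 called genes that the naming rule took here, 26 stayed called whichever array was left out, among them CXCL8, IL1A, TNFAIP3, ICAM1, C3, CCL2, CXCL10, IKBKE, NFKBIA, VIPR1 and MMP9. IL6 lost its call in 1 of the 6 such fits and SAMD9 in 6.

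**Figure D1:**
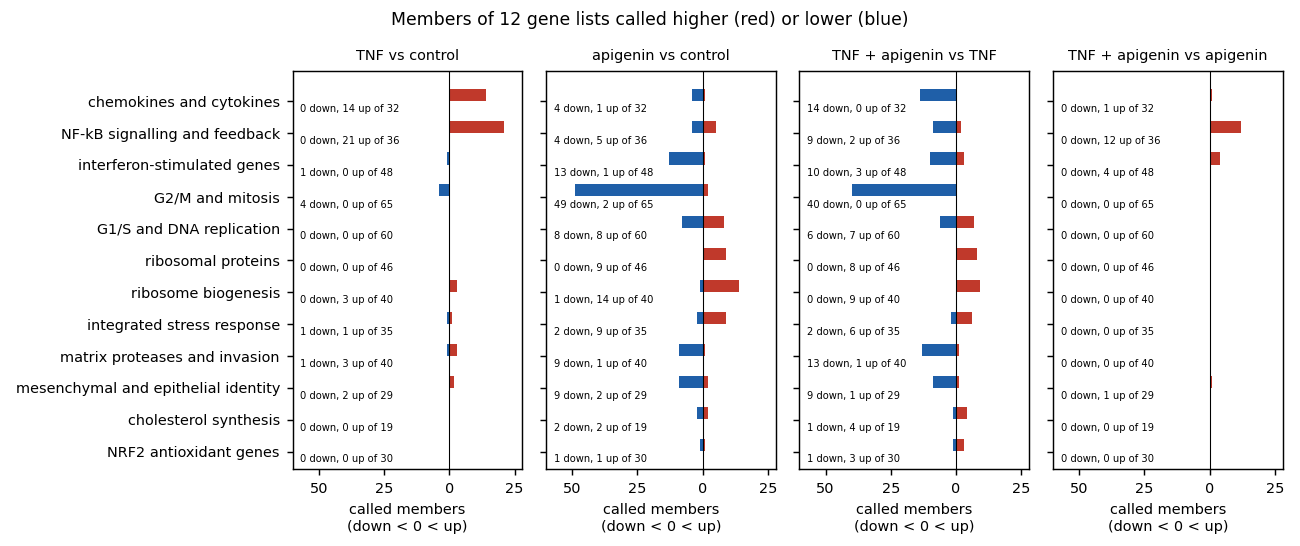
Number of called members of 12 gene lists in 4 comparisons (limma, adjusted p below 0.05); bars to the right of 0 count members called higher in the first-named group, bars to the left members called lower, and the text under each bar gives the counts and the number of measured members. The largest bar is the 49 of 65 G2/M and mitosis genes lower with apigenin, and 14 of 32 chemokine and cytokine genes were higher with TNFα and 14 lower when apigenin was added to it.

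The second comparison asked what apigenin alone changed. Genes of mitosis fell together: PLK1, the mitotic kinase, went from 7.68 ± 0.17 in control to 5.54 ± 0.14 (log2 fold change -2.14, SE 0.13, adjusted p = 1.1e-06, n = 3 per group). The kinesins KIF20A (-1.86) and CENPE (-1.85), the centrosomal kinase NEK2 (-1.74) and cyclin B1 (CCNB1, -1.28) fell with it. In the G2/M and mitosis list 49 of 65 members fell and 2 rose, 56 and 2 when adjusted over the list alone (median -0.72, camera adjusted p = 7.8e-37; adjusted p = 0.0727 with an estimated correlation). The cyclin-dependent kinase inhibitor CDKN1A rose by 1.16 (SE 0.14, adjusted p = 1.8e-04). Genes of G1/S and DNA replication went both ways, 8 of 60 higher and 8 lower, with a median of 0.05 (adjusted p = 0.489). The origin recognition gene ORC6 rose by 1.35 and cyclin E1 (CCNE1) by 1.17, while the polymerase subunit POLE2 fell (-0.83) and the replicative helicase gene MCM2 differed by -0.00 (SE 0.12, adjusted p = 0.996).

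Among the called genes that the naming rule admits, the 8 largest increases with apigenin began with ARRDC4, an arrestin-domain gene that responds to glucose (2.76, SE 0.30, adjusted p = 7.1e-05), and the immediate early gene ARC (2.55). They went on with the small G protein RASD1 (2.48), SLFN5 (2.40), the zinc exporter SLC30A1 (2.35, SE 0.13, adjusted p = 4.9e-07), the immediate early gene EGR1 (2.25), KICS2 (2.19) and the stress gene GADD45B (2.19). The 8 largest decreases under the same rule were in the sugar transporter SLC2A12 (-2.40), the xenobiotic-metabolising cytochrome CYP1B1 (-2.39, SE 0.16, adjusted p = 1.9e-06), CAVIN2 (-2.39), IGFBP1 (-2.39), the cadherin FAT4 (-2.20), the histone gene H2BC14 (-2.17), PLK1 and the phosphodiesterase PDE7B (-2.10). Metallothioneins MT1F (1.21) and MT1E (1.06), which bind zinc and copper, rose, and their list did not pass with camera but passed with fry, which asks whether the list itself moved (2 of 9 members higher, adjusted p = 0.108 with camera and 0.00752 with fry).

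Several lists besides mitosis moved with apigenin, and none of the 9 called lists, mitosis included, held with an estimated correlation. With fry 8 of the 9 stayed called. Interferon-stimulated genes fell (13 of 48 lower and 1 higher, 19 and 2 over the list alone, median -0.35, adjusted p = 1.2e-06; adjusted p = 0.335 with an estimated correlation), among them SAMD9L (-1.89), the RNA sensor RIGI (-1.42) and IFIT3 (-1.40). Of the mesenchymal and epithelial identity list 9 of 29 fell and 2 rose (adjusted p = 7.7e-04; adjusted p = 0.410 with an estimated correlation). The list pools genes of both identities, so its direction does not tell which identity changed. The ligand TGFB2 (-1.82) and its receptors TGFBR1 (-1.26) and TGFBR2 (-0.99) fell, and SNAI1, a repressor of epithelial genes, rose (1.60). Of the matrix protease and invasion list 9 of 40 fell and 1 rose (adjusted p = 0.0263; adjusted p = 0.750 with an estimated correlation), with urokinase PLAU at -1.57 (SE 0.11, adjusted p = 2.8e-06), ADAM10 at -0.94 and PLAT at -0.90. The integrated stress response rose (9 of 35 higher, 2 lower, adjusted p = 2.1e-04; adjusted p = 0.335 with an estimated correlation), with SESN2 at 1.36, asparagine synthetase ASNS at 1.09 and the amino acid transporter subunit SLC3A2 at 0.95. Its member XPOT went the other way, reading 8.44 to 8.81 in control and 7.62 to 7.90 with apigenin. The unfolded protein response rose (8 of 29 higher, 1 lower, adjusted p = 2.6e-04; adjusted p = 0.536 with an estimated correlation), with the sensor kinase ERN1 at 1.11, the chaperone HSPA5 at 0.87 and XBP1 at 0.82. CREB3L2, of this list, was lower, at 4.84 to 5.39 in control and 3.91 to 4.31 with apigenin.

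Ribosome-related lists rose with apigenin. Ribosome biogenesis genes rose (14 of 40 higher, 1 lower, median 0.32, adjusted p = 2.2e-09; adjusted p = 0.335 with an estimated correlation), led by BYSL (1.05) and NOP2 (0.88). So did ribosomal proteins (9 of 46 higher, none lower, median 0.26, adjusted p = 8.1e-11; adjusted p = 0.109 with an estimated correlation), led by RPLP1 (1.53) and RPL37 (1.04). All 46 measured ribosomal protein genes, of 76 listed, had a positive fold change. RPLP1 stood at only 3.14 to 3.30 on the control arrays, and the list medians there were 5.19 to 5.28. The scale reached 12.495. Whether low-reading probe sets follow the main ribosomal protein mRNAs was not checked. The kept probe sets of the panel genes ACTB (3.22 to 3.80) and GAPDH (4.84 to 5.07) also read low over the 12 arrays. Small nucleolar RNAs, which guide the modification of ribosomal RNA, rose as well (15 of 173 higher, none lower, median 0.45, adjusted p = 8.4e-11; adjusted p = 0.586 with an estimated correlation), and SNORD99 rose by 1.72. The array medians of the small nucleolar RNA list were 5.69, 5.44 and 5.33 in control and 6.34, 5.77 and 6.09 with apigenin, against 4.75 to 5.96 within the TNFα group. Markers of leukocytes, fibroblasts and endothelium did not pass: leukocyte markers had none of 17 called in the limma fit over all genes or adjusted over the list alone (median 0.08, adjusted p = 0.489), fibroblast and endothelial markers none of 13 (median -0.07, adjusted p = 0.998). Of the luminal breast epithelial markers 3 of 16 fell and 1 rose (median -0.17, adjusted p = 0.141 with camera and 0.0142 with fry), with SPDEF at -1.31 and KRT19 at -0.95.

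Apigenin against control gave 2342 called genes, 936 higher and 1406 lower, of which 444 changed at least 2-fold. Without control replicate 3 the lower calls were no longer the majority, with 982 higher and 897 lower. They stayed the majority without each of the other 5 arrays, with 638 higher and 1116 lower without control replicate 1 and 638 and 1412 without control replicate 2. The calls were 634 higher and 900 lower without apigenin replicate 1 (1534 in all), 824 and 922 without apigenin replicate 2, and 607 and 1324 without apigenin replicate 3. With the small nucleolar RNA median of each array as a covariate, chosen after seeing the data, it was 1290. Of these 679 were higher and 611 lower, so the share of higher calls moved from 40.0% to 52.6%, and 1195 of these genes were among the 2342.

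**Figure D2:**
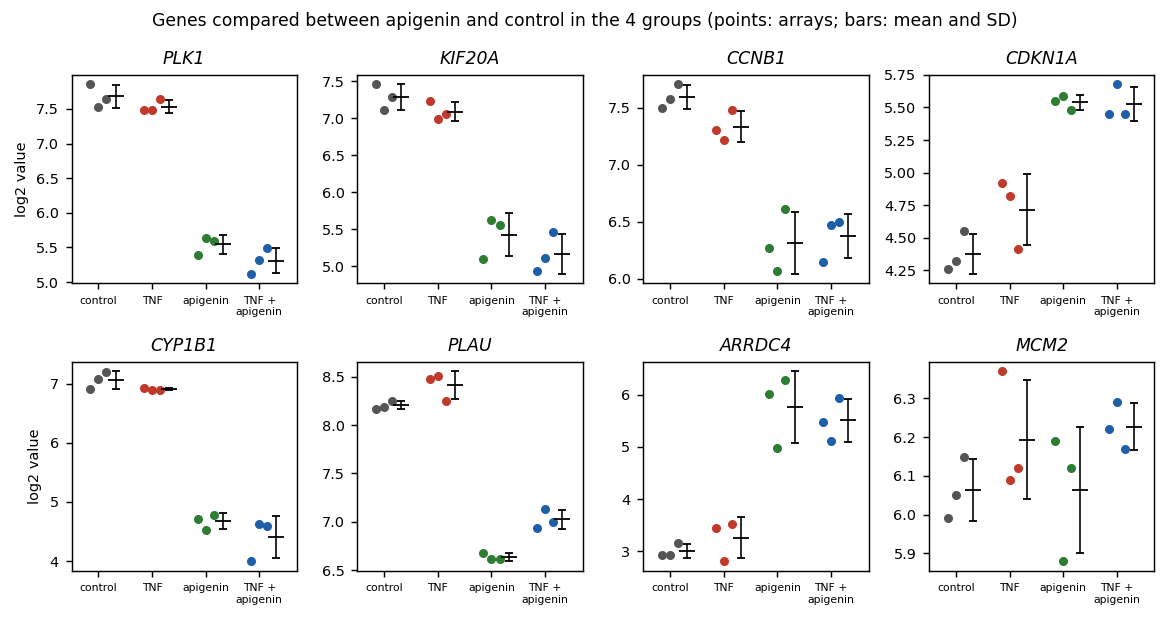
Log2 expression values of 8 genes on each of the 12 arrays; points are arrays (n = 3 per group), and the bars beside them show the mean and SD. PLK1 lay at 5.54 with apigenin and 7.68 in control (means), and the values with and without apigenin did not overlap for PLK1, KIF20A, CCNB1, CDKN1A, CYP1B1, PLAU or ARRDC4; the groups overlapped for MCM2.

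The third comparison asked what apigenin changed in cells that also received TNFα. IL1A was lower with both than with TNFα alone, 2.47 ± 0.23 against 6.20 ± 0.11 (log2 fold change -3.73, SE 0.15, adjusted p = 2.8e-08, n = 3 per group). The cytokine IL24 (-2.53), the kinase IKBKE (-2.29, SE 0.27), complement C3 (-2.16), the hyaluronidase CEMIP (-2.45), CYP1B1 (-2.50), CAVIN2 (-2.24) and PLK1 (-2.22) were lower too. Of the chemokines and cytokines 14 of 32 were lower and none higher, 16 lower over the list alone (median -0.45, camera adjusted p = 1.1e-09; adjusted p = 0.0508 with an estimated correlation). CXCL11 differed by -1.83, the death ligand TNFSF10 by -1.78, IL6 by -1.44, CXCL10 by -1.40, CXCL8 by -1.21 and CCL2 by -1.17 (SE 0.14, adjusted p = 2.1e-04). The list of NF-κB signalling and feedback genes went less one way, with 9 of 36 members lower and 2 higher (median -0.09, adjusted p = 0.190): TNFAIP3 fell by 0.78 (SE 0.15, adjusted p = 0.00425), GADD45B rose by 2.08, and NFKBIA differed by -0.23 (SE 0.15, adjusted p = 0.417).

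Besides the chemokines and cytokines, 9 lists were called in this comparison. G2/M and mitosis genes fell, 40 of 65 with none higher (median -0.52, adjusted p = 4.7e-26; adjusted p = 0.0882 with an estimated correlation). Of the matrix protease and invasion list 13 of 40 fell and 1 rose (adjusted p = 2.0e-04; adjusted p = 0.481 with an estimated correlation), with MMP1 at -1.81, PLAU at -1.39, MMP9 at -1.16 and the collagen cross-linking enzyme LOX at -1.07. The mesenchymal and epithelial identity list, which pools both identities, fell (9 of 29 lower, 1 higher, adjusted p = 1.9e-05; adjusted p = 0.370 with an estimated correlation), and so did the interferon-stimulated genes (10 of 48 lower, 3 higher, adjusted p = 5.3e-04; adjusted p = 0.481 with an estimated correlation). In the glycolysis and hypoxia list 9 of 34 fell and 2 rose (adjusted p = 0.0130; adjusted p = 0.481 with an estimated correlation), with PFKFB4 at -0.85 and BNIP3L at -0.74 beside TXNIP at 0.80. Ribosomal proteins (8 of 46 higher, none lower, adjusted p = 3.0e-10; adjusted p = 0.0882 with an estimated correlation) and small nucleolar RNAs (8 of 173 higher, none lower, adjusted p = 5.0e-12; adjusted p = 0.481 with an estimated correlation) rose. The array medians of the latter with both treatments were 5.86, 5.85 and 5.90. Ribosome biogenesis genes (9 of 40 higher, none lower, adjusted p = 2.4e-04; adjusted p = 0.481 with an estimated correlation) and the integrated stress response (6 of 35 higher, 2 lower, adjusted p = 0.0150; adjusted p = 0.481 with an estimated correlation) rose too. The stress response list lost its call without the arrays numbered 3, a fit chosen after seeing the data (camera adjusted p = 0.0905).

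In all, 2085 genes were called between the combined treatment and TNFα, 867 higher and 1218 lower, with 370 changed at least 2-fold. Without TNFα replicate 3 the lower calls were no longer the majority, with 780 higher and 749 lower. The calls were 542 higher and 736 lower without TNFα replicate 1 (1278 in all). Without replicate 1, 2 and 3 of the combined treatment they were 527 and 664 (1191 in all), 674 and 748, and 524 and 997. With the small nucleolar RNA covariate chosen after seeing the data the count was 1057 (592 higher, 465 lower). The apigenin response with TNFα shares no array with the response without it. Across the 20572 genes their fold changes correlated at r = 0.763 (Spearman's rho 0.617, orthogonal slope 0.96). In both, 565 genes were called higher against 39.4 for independent lists, 822 were called lower against 83.2, and 2 were called in opposite directions.

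Of the 160 genes that TNFα raised, 92 were lower when apigenin was added, where independent lists of these sizes would share 9.47. These comparisons share the TNFα arrays, which by itself makes their fold changes oppose each other. The correlation across genes was -0.251 against -0.500 for simulated unchanged groups, and the covariance was -0.0214 against -0.0145 simulated. Part of the overlap may come from the shared arrays, and 3 arrays could not be split into separate sets of at least 2 for each comparison. Falls with apigenin alone enter the overlap too, so it does not measure a held-back TNFα response. TNFSF10 read 7.67 to 7.82 in control and 6.35 to 6.55 with apigenin alone, and IKBKE 4.09 to 4.74 and 2.33 to 3.60. With apigenin alone 4 of 32 chemokines and cytokines were called lower and 1 higher, and of 36 NF-κB genes 4 lower and 5 higher.

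**Figure D3:**
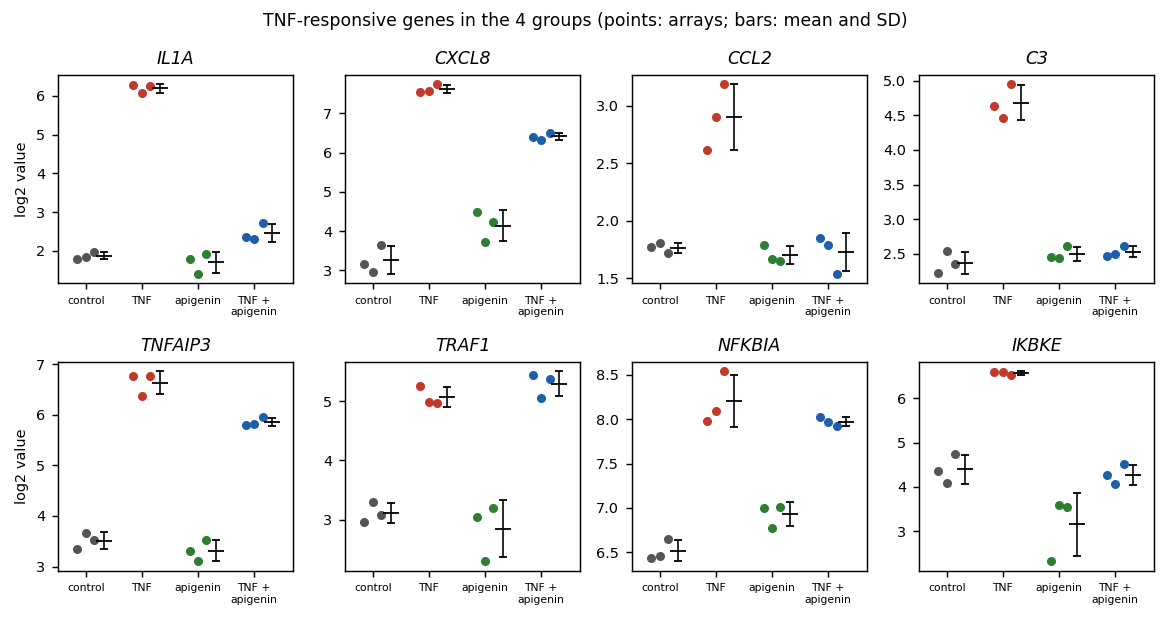
Log2 expression values of 8 TNFα-responsive genes on each of the 12 arrays; points are arrays (n = 3 per group), and the bars beside them show the mean and SD. With both treatments IL1A lay at 2.47 (mean) against 6.20 with TNFα alone, whereas TNFAIP3 lay at 5.85 against 6.64 and NFKBIA at 7.97 against 8.20.

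The fourth comparison asked what TNFα changed in the presence of apigenin. TNFAIP3 rose from 3.31 ± 0.21 with apigenin alone to 5.85 ± 0.09 with both (log2 fold change 2.54, SE 0.15, adjusted p = 2.7e-06, n = 3 per group). TRAF1 rose by 2.45 (SE 0.20), CXCL8 by 2.27 (SE 0.19), the inhibitor NFKBIE by 2.01 (SE 0.19), TNFRSF9 by 1.94, ICAM1 by 1.63 and CD83 by 1.48. Of the NF-κB list 12 of 36 rose and none fell, 23 over the list alone (median 0.48, camera adjusted p = 3.6e-32; adjusted p = 0.0714 with an estimated correlation). Of the chemokines and cytokines only CXCL8 was called, 7 of 32 over the list alone (median 0.23, adjusted p = 2.0e-05; adjusted p = 0.136 with an estimated correlation). CCL2 differed by 0.02 (SE 0.14, 95% interval -0.28 to 0.33, adjusted p = 0.991), IL1A by 0.76 (SE 0.15, adjusted p = 0.0789) and IKBKE by 1.12 (SE 0.27, adjusted p = 0.199). NFKBIA rose by 1.05 (SE 0.15, adjusted p = 0.00702) and lost its call in 1 of the 6 fits with an array left out. The 43 called genes were all higher; 1489 genes had an unadjusted p below 0.05. The count was 15 without apigenin replicate 1, 19 without apigenin replicate 2, and 23, 19 and 18 without replicate 1, 2 and 3 of the combined treatment.

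Whether the TNFα response itself differed with apigenin was tested as an interaction, and 11 genes passed. The response of IL1A was 4.33 without and 0.76 with apigenin (interaction -3.57, SE 0.21, adjusted p = 4.7e-06), and that of C3 was 2.31 and 0.03 (interaction -2.29, SE 0.20, adjusted p = 2.0e-04). CXCL8 (-2.09, adjusted p = 0.0218), CXCL11 (-1.51), IL24 (-1.47), MMP9 (-1.39), the axonal contact gene CNTNAP1 (-1.46) and the tight junction gene CLDN1 (-1.12) also responded less. For CXCL8 apigenin alone had raised the level (0.88, SE 0.19, adjusted p = 0.00949; 0.0518 without apigenin replicate 1), so part of its interaction is a higher starting level. The cytokine list as a whole did not pass with apigenin alone (1 of 32 higher, 4 lower, adjusted p = 0.388). LOC100287834 (-2.51), named outside the rule after the values were seen, completed the 9 genes with a lower response. SAMD9L (1.37) and VIPR1 (1.18) had positive interactions. The TNFα response of VIPR1 was -1.50 without and -0.33 with apigenin, a weaker fall, and that of SAMD9L was -0.68 and 0.68. For CCL2 (-1.11, SE 0.20, adjusted p = 0.131), CXCL10 (-1.41, SE 0.30, adjusted p = 0.313) and TNFAIP3 (-0.58, SE 0.21, adjusted p = 0.999) the difference of response was not called. The chemokine and cytokine list had a lower response with apigenin (4 of 32 called, 12 over the list alone, median -0.26, camera adjusted p = 1.5e-14; adjusted p = 0.0114 with an estimated correlation).

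The calls of IL1A and C3 held in all 26 alternative fits run for them, 12 of which left out 1 array, with adjusted p up to 0.00409 and 0.0302. The other 8 genes of the naming rule lost theirs in 9 to 12 of the 12 fits with an array left out. Without control replicate 1, 2 or 3 there were 3, 2 and 6 called genes, and without TNFα replicate 1, 2 or 3 there were 4, 3 and 3. Without apigenin replicate 1, 2 or 3 there were 4, 3 and 3, and without each replicate of the combined treatment 2. Over all genes, the TNFα responses with and without apigenin, which share no array, correlated at r = 0.406 (Spearman's rho 0.317) with an orthogonal slope of 0.60. Of the 205 genes called without apigenin 189 had the same sign with it, and 30 of the 160 higher ones were called higher again against 0.334 for independent lists. The median ratio of the responses was 0.42, a ratio lowered by having chosen the genes on the first response.

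**Figure D4:**
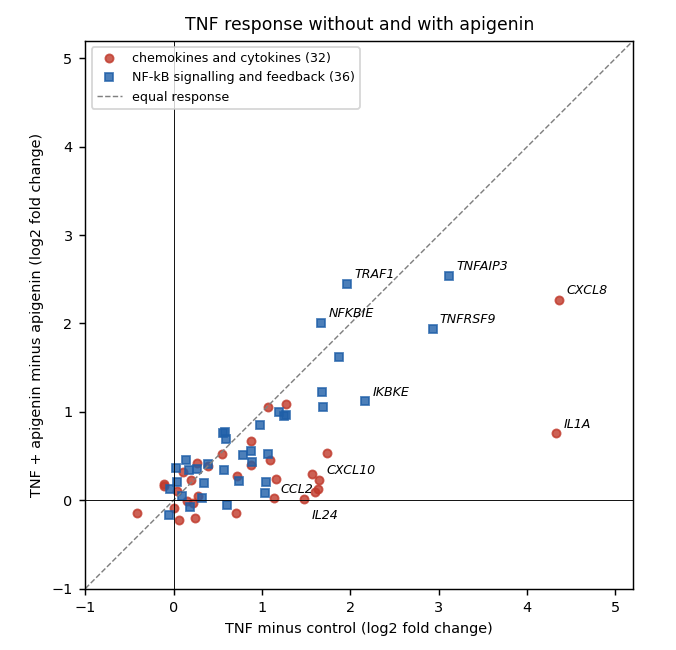
Log2 fold change of TNFα against control (horizontal) and of the combined treatment against apigenin (vertical) for the 32 measured chemokine and cytokine genes and the 36 NF-κB signalling and feedback genes; the dashed line marks an equal response. IL1A lies at 4.33 and 0.76 and CXCL8 at 4.36 and 2.27, below the line, while TRAF1 lies at 1.96 and 2.45, above it.

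The combined treatment against untreated cells showed both patterns side by side. CXCL8 was higher by 3.15 (SE 0.19, adjusted p = 6.5e-07), SLFN5 by 2.87, ARRDC4 by 2.51 and TNFAIP3 by 2.34, and CYP1B1 (-2.66), CAVIN2 (-2.65), PDE7B (-2.43) and PLK1 (-2.37) were lower. The NF-κB list rose (18 of 36 higher, none lower, median 0.54, adjusted p = 1.9e-18; adjusted p = 0.171 with an estimated correlation), and the G2/M and mitosis list fell (45 of 65 lower, 1 higher, median -0.65, adjusted p = 1.4e-36; adjusted p = 0.0742 with an estimated correlation). Ribosome biogenesis genes rose (22 of 40, none lower, median 0.53, adjusted p = 2.3e-13; adjusted p = 0.192 with an estimated correlation). CCL2 differed from control by -0.04 (SE 0.14, adjusted p = 0.924). Luminal markers fell (3 of 16 lower, 1 higher, adjusted p = 0.0265; adjusted p = 0.211 with an estimated correlation), with SPDEF at -1.50, KRT19 at -1.22 and KRT18 at -0.79. Without the arrays numbered 3, chosen after seeing the data, the luminal list lost its call (camera adjusted p = 0.0905). There were 2576 called genes, 1471 higher and 1105 lower. The calls were 980 higher and 1073 lower without control replicate 2, and 1640 and 769 without control replicate 3. Without replicate 1, 2 and 3 of the combined treatment they were 1037 and 693, 1214 and 721, and 946 and 891. Quantile normalisation called 1300 higher and 2049 lower, so the share of higher calls moved from 57.1% to 38.8%.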

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

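The response to TNFα differed with apigenin for 11 genes and 8 gene lists by the test of the difference itself. Of the tests in this part, the comparison of response ratios and those on ribosome-related RNA were chosen after the result was seen. The interaction was -3.57 for IL1A, -2.51 for LOC100287834, -2.29 for C3, -2.09 for CXCL8, -1.51 for CXCL11, -1.47 for IL24, -1.46 for CNTNAP1, -1.39 for MMP9, -1.12 for CLDN1, 1.18 for VIPR1 and 1.37 for SAMD9L. Among lists the response was lower for chemokines and cytokines (adjusted p = 1.5e-14), NF-κB signalling and feedback (2.9e-05), ribosome biogenesis (7.8e-04), the unfolded protein response (0.0243) and antigen presentation and adhesion (0.0394). A positive interaction was called for G2/M and mitosis (6.9e-10), interferon-stimulated genes (0.0203) and homologous recombination and Fanconi repair (0.0435). For G2/M and mitosis TNFα lowered the list without apigenin (camera adjusted p = 7.1e-12). With apigenin, which alone had lowered the list, it was not called (camera adjusted p = 0.778). There the array medians of the list did not fall with TNFα. They were 6.37, 6.33 and 6.42 with apigenin alone and 6.41, 6.41 and 6.50 with both. The interferon and repair lists were called in neither of these TNFα comparisons. With an estimated correlation, only the chemokine and cytokine list stayed below 0.05. Without the arrays numbered 3, chosen after seeing the data, the repair list lost its call (0.629).

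The weaker TNFα response of cytokine genes with apigenin was weighed against measurement limits. The deposited values were not compressed on the apigenin arrays. The mean SD over genes on those 6 arrays was 0.996 of that on the other 6. Between-array normalisation, which the close quartiles leave possible, would bring the SDs together. The ratio therefore cannot decide on compression before that step. A floor stays open for part of the pattern: in the combined group 4 of the 9 genes with a lower response (CXCL8, CNTNAP1, CLDN1 and LOC100287834) lay above the median of all genes, and 5 lay below it. For CXCL11, IL1A, C3 and MMP9 the controls read below it too, so a fall with apigenin alone could be hidden. For IL24 the control stood at 3.85 and a fall with apigenin alone was called (-1.06, adjusted p = 0.00103 in limma), which ended below the median and may be larger than measured. A candidate biological explanation is that apigenin holds back the induction of cytokine genes more than that of NF-κB feedback genes. The fraction of the log2 response left with apigenin had a median of 0.26 over 14 TNFα-raised cytokine genes and 0.66 over 21 TNFα-raised NF-κB genes (two-sided permutation p = 0.0107 with 100000 permutations across genes, which are not independent). This does not decide for that explanation: the test came after the lower response of the cytokine list was known, and 6 of the 14 cytokine genes against 1 of the 21 NF-κB genes lay below the median of all genes in control, where a hidden fall with apigenin alone would lower the ratio too. Over the 8 and 20 of these genes with controls above that median, the medians were 0.42 and 0.70 (two-sided permutation p = 0.0600). This choice is not free of the response either. The genes were taken because TNFα raised them, and the control level enters the ratio. The floor, compression before normalisation and the candidate explanation all stay open.

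A second pattern is the rise of ribosomal protein and small nucleolar RNA lists with apigenin. Different recovery of small RNA between preparations may raise small nucleolar RNAs. For the ribosomal proteins it stays open. With the small nucleolar RNA median as a covariate their median log2 fold change went from 0.26 to 0.23 (adjusted p = 7.3e-08 by camera in limma). With an estimated correlation the list passed neither without the covariate (adjusted p = 0.109) nor with it (adjusted p = 0.248). For the small nucleolar RNAs themselves, recovery and treatment cannot be told apart, since the widest range of array medians within a group was 2.08 times the difference between apigenin and control. The long host transcripts that carry them, a family chosen after the values were seen, were higher too (9 of 13 called, median 0.67, adjusted p = 0.0529 by camera in limma with an estimated correlation over 18 tests of 3 families in 6 comparisons, 0.00294 before adjustment). Higher transcription of the hosts is a hypothesis that passed before this adjustment and not after it.

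Other divisions of the same arrays were counted. Each comparison of 3 arrays with 3 allows 10 splits, too few for a share under 0.05. The real split gave 205 called genes for TNFα against control and the highest other split 1. It gave 2342 for apigenin against control (highest other 1), 2085 for the combined treatment against TNFα (1), 43 against apigenin (0) and 2576 against control (0), and in each of the 5 comparisons 1 split, the real one, gave as many. Every other split mixes arrays of both groups, which places a true difference in the residual and lowers its count. The low counts of the other splits therefore do not exclude chance. For the interaction 3 of 100 random divisions of the 12 arrays, the real one included, gave at least the 11 called genes, and the highest other division gave 351. That division called many times the real number, which points to the structure of the samples: a random division places the large apigenin effect in the residual or in the interaction. These divisions therefore do not show whether chance can be excluded.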

How the results depend on the processing

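No called gene of the naming rule changed direction in the alternative fits, and no called list did so apart from the small nucleolar RNA list under the covariate made from its own median, which is left out of the counts below. Under that covariate it turned lower in 3 comparisons: apigenin against control (adjusted p = 0.424), the combined treatment against TNFα (0.861), and the combined treatment against control, where it was called lower (0.0143 by camera in limma). Over 552 tested values of these genes, 11689 alternative fits kept the call or its absence in 10471 cases, lost a call in 1205 and gained one in 13. With 1 array left out, 538 of 3516 lost a call. The fit with all probe sets read each gene from its probe set with the lowest p, so a disagreeing probe set could hardly reverse a call. ATG9A, taken by the naming rule, had a probe set of opposite sign for apigenin and for the combined treatment, each against control. For the lists 1006 of 1146 were unchanged, 117 lost and 23 gained a call. An estimated correlation removed 61 calls. With fry, 4 of 15 called lists stayed called for TNFα against control and 8 of 9 for apigenin against control. For the combined treatment these were 7 of 10 against TNFα, 2 of 10 against apigenin and 11 of 12 against control. For the interaction 1 of 8 stayed called.

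For TNFα against control (205 called genes) the count was 121 without variance moderation, 331 with array weights, 71 at 2-fold or more, 73 with only the 2 groups, 328 with a filter at a log2 value of 4 and 85 without the arrays numbered 3, and 98 to 314 with 1 array left out. For apigenin against control (2342) it was 444 at 2-fold or more, 1505 without the arrays numbered 3, 1290 with the small nucleolar RNA covariate and 1534 to 2050 with 1 array left out. For the combined treatment against TNFα (2085) these were 370, 1288, 1057 and 1191 to 2063. Against apigenin (43) the count was 24 without moderation, 77 with array weights, 22 at 2-fold or more, 21 with only the 2 groups, 68 with the filter at 4, 15 without the arrays numbered 3, 26 with the covariate and 15 to 31 with 1 array left out. Against control (2576) it was 488 at 2-fold or more and 1730 to 2409 with 1 array left out. For the interaction (11) it was 5 with median centring, 3 with trend and robust variance, 2 without moderation, 2 without the arrays numbered 3, 5 with the covariate and 2 to 6 with 1 array left out. The filter at 4, the fit without the arrays numbered 3 and the covariate were chosen after seeing the data.

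The correlation of the TNFα responses ran from 0.307 to 0.435 and that of the apigenin responses from 0.715 to 0.752 with 1 array left out (jackknife SE 0.125 and 0.035).

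Samples with the same number in different groups share only a number in the labels. With the replicate number as a block the counts were 632 for TNFα against control, 3501 for apigenin against control, 3315, 100 and 3819 for the combined treatment against TNFα, apigenin and control, and 14 for the interaction, and every called gene of the model without the block stayed called. Calls were gained by 4 values of the named genes: IL1A for the combined treatment against apigenin (adjusted p = 0.0120 in limma), NFKBIA (0.0467) and HMOX1 (0.0192) for apigenin against control, and CYP1A1 for the combined treatment against control (0.0299). In 3 lists the camera adjusted p in limma went above 0.05 with the block: matrix proteases and invasion for apigenin against control (0.0551, and 0.0984 without the arrays numbered 3), apoptosis machinery for TNFα against control (0.0672) and antigen presentation and adhesion for the interaction (0.0554). After removal of the group means, all 12 arrays had their highest mean correlation with the arrays of their own number. This is a hint from the data that the numbers mark shared handling. The same-number correlations ran from 0.018 to 0.464 and the others from -0.442 to 0.102. For number 1 they ran only from 0.018 to 0.102, so the hint is weak there. For number 2 they ran from 0.201 to 0.376 and for number 3 from 0.302 to 0.464.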

Other observations

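All tests on gene families in this part were chosen after the data were seen. Genes named outside the naming rule are SNHG1, SNHG12, SNHG19, GAS5, ZNF75A, ZNF468, ZNF622 and ZNF121. Of 13 measured long host transcripts of small nucleolar RNAs 9 rose with apigenin and none fell, but the family did not pass with an estimated correlation (adjusted p = 0.0529 by camera in limma over 18 tests). SNHG19 rose by 1.79, SNHG12 by 1.61, SNHG1 by 1.19 and GAS5, a transcript that accumulates when growth stops, by 0.67. In TNFα-treated cells 6 of the 13 were higher and 1 lower with apigenin. Probes at microRNA loci moved at single loci while their list did not (8 of 684 higher, 6 lower, adjusted p = 0.492). MIR100 rose by 3.57 (SE 0.20) and MIR3143 by 2.56 with apigenin, and by 3.26 and 2.51 in TNFα-treated cells, where MIR21 rose by 2.04. Such a probe set can read the host or primary transcript, so these values are no level of the mature microRNA.

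Some lists that one would look at for a plant flavone were not called by camera with apigenin alone. Of the NRF2 antioxidant genes 1 of 30 rose and 1 fell (adjusted p = 0.490), with HMOX1 at 0.54 (SE 0.18, adjusted p = 0.0672) and NQO1 at -0.24 (adjusted p = 0.271). Of the aryl hydrocarbon receptor and xenobiotic genes 1 of 15 rose and 3 fell (adjusted p = 0.108 with camera), and 11 of 15 had a negative fold change; the list was lower with fry (adjusted p = 0.0159 in limma); CYP1B1 fell by 2.39 while CYP1A1 differed by -0.46 (adjusted p = 0.156). Of the p53 target genes 6 of 30 rose and 6 fell (adjusted p = 0.608): SESN2 and CDKN1A rose, by 1.36 and 1.16, and DDB2 fell by 0.96. Of the cholesterol synthesis genes 2 of 19 rose and 2 fell (adjusted p = 0.995).

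Zinc finger genes with ZNF symbols, 465 of which were measured, leaned upwards with apigenin: 58 were called higher and 8 lower, the median was 0.16, and 317 had a positive fold change. In TNFα-treated cells 76 were higher and 9 lower with apigenin. ZNF75A rose by 1.67, ZNF468 by 1.58, ZNF622 by 1.48 and ZNF121 by 1.16. Their low level is argued against as the cause, because 0 of 10000 random lists matched on mean level had a median as high (highest 0.03). The RNA composition of the arrays stays open. With the small nucleolar RNA covariate the median went from 0.16 to 0.22, with adjusted p = 1.9e-10 by camera in limma over the 18 family tests (3.2e-11 before adjustment), but with an estimated correlation the family did not pass with the covariate either (0.0745 before adjustment). The hypothesis that apigenin raises the family as a whole did not pass when the correlation among members was estimated (adjusted p = 0.302 by camera in limma, 0.151 before adjustment; estimated correlation 0.138). Joint variation of the family between arrays is therefore not excluded as a source of the shift. Cross-hybridisation of related sequences may add to such variation and was not tested. The apigenin comparison in TNFα-treated cells, which shares no array with this one, leaned the same way (median 0.18). It did not pass with an estimated correlation either (adjusted p = 0.236 by camera in limma).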
